A study of Mus musculus with 10 samples.

How the data were processed

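RNA was measured by sequencing in 10 libraries from the outflow vein of mouse arteriovenous fistulas, 5 after antibody and 5 after vehicle. Per the labels' protocols, libraries were made from 0.5 µg of total RNA with the TruSeq V2 kit, and mm10 is the build named in the submitters' processing notes. The aligner, the counting tool, the use of strand and the annotation release are not given in the sources used here. Samples were grouped by their titles and descriptions, and replicate numbers are those of the titles.

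The file is a single table of 43346 genes with 10 columns of RPKM, reads scaled by gene length and library total, per the file headers. The authors also deposited averages of the RPKM columns, a fold ratio of the antibody to the vehicle average and an unadjusted p-value per gene. Checked against the values, the authors' deposited p-value equals an equal-variance test on unlogged RPKM to within 2.72e-12. The deposited RPKM values correspond to whole reads divided by gene length plus 1 bp and by the sum of reads over the table. Multiplying back gave whole reads for 100% of the values within 0.001 (largest distance 3.54e-08), so the depth of each library is known: 4282872 to 34271554 reads. Depth set the precision of low genes, since 3 reads correspond to 0.70 CPM in the shallowest and 0.0875 CPM in the deepest library. Of the gene IDs, 42462 were named from the reference gene table and 884 kept the name in the file. Coordinates are those of the file, and 33460 of the 42462 IDs (78.8%) had the same coordinates in GENCODE M21. In 3673 genes all 10 libraries were at 0. All mitochondrially encoded genes were at 0 in each library, so that list could not be tested. Where genes overlap or have antisense partners, or have near-identical copies, reads cannot be told apart here.

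A few non-coding genes took a large and variable share of reads. The 57-bp gene Gm23935 took 2.11% to 18.3%, a lincRNA overlapping a ribosomal RNA repeat 3.77% to 11.6%, and Rn7sk, Rpph1 and Rmrp together 0.979% to 2.18%. Protein-coding genes took 64.1% to 79.9%. Composition was therefore scaled with trimmed means of M values (TMM), computed from the recovered reads by a function written for this purpose. The factors ranged from 0.841 to 1.13.

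Genes were kept when at least 5 libraries reached the CPM that 10 reads represent in a library of median depth (0.513 CPM) and at least 15 reads were found over all libraries, which left 17859 genes, 14658 of them protein-coding. Before the data were examined, limma had been named for the case that the table held normalized values. Since the unit is RPKM, edgeR and DESeq2, which model raw counts, were not used. The main test was limma 3.58.1 in R 4.3.3 with a trended variance on log2(scaled RPKM + 0.5), with group as the only term, coded antibody minus vehicle, two-sided, Benjamini-Hochberg adjusted over all genes kept, and called at an adjusted p below 0.05. Standard errors and 95% intervals are those of limma.

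The 31 gene lists were fixed before the data were examined, and 30 had at least 3 tested members. They were tested with camera at a preset correlation of 0.01, adjusted over the 30 lists, then with an estimated correlation and with fry. Lists share members in part, so their tests are not independent. The library means of each list were compared with an exact two-sided permutation test over the 252 assignments of 5 against 5, whose smallest possible p is 0.00794. Components were computed from log2 CPM with a prior count of 2.

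Genes named in the text follow a rule set before the data were examined. It took Cx3cr1 and Cx3cl1; the genes past the threshold with an average log2 CPM of at least 1 and non-overlapping groups, up to 10 per direction by size; where fewer passed, the genes of smallest unadjusted p per direction at that expression, up to 10, given as values, with predicted symbols passed over; and for each list up to 4 members of smallest p. The kidney genes, Acta1, Ckm, Sln, Mb, S100a9, Hbb-bs, the abundant non-coding genes and Gm27598 were named after their values were seen. A gene that the rule selects and a relation among kidney genes are not reported here.

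The whole procedure was tested on simulated data with 200 genes changed by known folds at the real depths and spread. The changed genes were drawn from well-read genes only, so the recovery of low genes was not measured. Of 50 genes per fold, 18 were recovered at 1.5-fold, 38 at 2-fold, 46 at 3-fold and 49 at 4-fold, with 7 of 17659 unchanged genes called. A list raised 1.5-fold had a camera adjusted p of 2.71e-22, and 0 of 30 unchanged lists were called where genes were simulated as independent, which real genes are not. No pair of libraries of a group agreed within sampling noise: the chi-square of their reads divided by its degrees of freedom was at least 11.9.

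Alternatives covered scaling by medians of ratios or by totals only, other filters, each library left out, the replicate number as a block, limma-voom with and without quality weights, other thresholds, an estimated list correlation and fry. Pseudocounts of 0.1 and 1, protein-coding genes only, the 3 libraries richest in muscle or the 4 highest in Kap left out, the muscle level as a covariate and thinning to 4282872 reads per library were added after the data were seen. Of the 126 splits of the libraries into 5 and 5, 100 were used, the real one included and the others drawn with seed 6. Thinning used seeds 5 and 7, and correlations used 100000 permutations with seed 8. Plots were drawn with matplotlib 3.10.9.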

Results

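The series measured RNA in the outflow vein of arteriovenous fistulas in mice. An arteriovenous fistula joins an artery directly to a vein, as is done in patients to give access for haemodialysis, and the vein wall then thickens under arterial flow. Per the labels, the mice carried a knock-in of human CX3CR1, the receptor for the chemokine fractalkine (Cx3cl1), on a strain given as C57. Chronic kidney disease was established 28 days before the fistula was made between the carotid artery and the jugular vein. The animals then received antibody at 30 mg/kg or vehicle into the peritoneum 2 times per week, and the outflow vein was taken on day 7. The treatment text names an antibody to human CX3CR1, whereas the series title and design text name a fractalkine antibody, so which of the pair was bound is not settled by the labels. There were 10 libraries, 5 from antibody-treated and 5 from vehicle-treated veins. The labels do not state that each library came from a separate animal, and p-values here measure the spread between these libraries.

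The libraries held 4282872 to 34271554 reads over the genes of the table. Antibody libraries held 1.31e+07 ± 7.11e+06 reads (SD, n = 5) and vehicle libraries 2.18e+07 ± 8.59e+06, a difference within the spread (exact two-sided permutation p = 0.119). The shallowest was antibody replicate 3 and the deepest vehicle replicate 4. A count of 0 allowed a level of up to 0.70 CPM in the shallowest library and 0.0875 CPM in the deepest, taking 3 reads as the limit and covering counting error only. Values below are means of RPKM after composition scaling, with SD and n = 5 per group, and fold changes are on the scale of log2(RPKM + 0.5), which understates changes of low genes.

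Neither the receptor nor its ligand differed detectably between the groups. Mouse Cx3cr1, the fractalkine receptor of monocytes and macrophages (chromosome 9, 119901616 to 120068283, mm10), was read in each library, with 73 to 390 reads. Its level was 3.28 ± 0.654 RPKM in antibody and 3.02 ± 1.20 RPKM in vehicle veins, a log2 difference of 0.17 (SE 0.25, limma adjusted p = 0.879, exact permutation p = 0.651). The 95% interval ran from 0.768-fold to 1.64-fold. Without vehicle replicate 2, whose level was 1.28 RPKM, the log2 difference was -0.06. The mouse gene was reported because the table lists mouse genes; how reads of the human knock-in sequence were assigned is not given in the sources used here, and the annotated span overlaps 5 other genes. Cx3cl1 (chromosome 8, 94772009 to 94782423) stood at 3.0 ± 0.526 RPKM in antibody and 2.90 ± 0.814 RPKM in vehicle veins, a log2 difference of 0.07 (SE 0.17, limma adjusted p = 0.935, exact permutation p = 0.738, 95% interval 0.802-fold to 1.37-fold). Its sign changed without antibody replicate 3 (-0.02) and without vehicle replicate 5 (-0.07).

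The question posed by the design was which transcripts of the fistula vein differ between antibody and vehicle. No gene passed the threshold. Among genes eligible for naming, those of smallest limma p higher in antibody veins were Madd, the acute-phase gene Saa3, Map4k2 and the NF-kappaB regulator Nfkbiz. Those of smallest p lower in antibody veins included the small GTPase Arl3, Ankrd35 and the creatine-synthesis enzyme Gamt. All of these tied at a limma adjusted p of 0.739. Of 17859 genes tested by limma with a trended variance, 0 had an adjusted p below 0.05 and 0 an adjusted p below 0.10, and the smallest adjusted p was 0.739. Leaving out single libraries also called 0 genes, but the smallest adjusted p was then 0.104 without antibody replicate 5 and 0.427 without vehicle replicate 2. At an unadjusted p below 0.05 there were 1166 genes, 634 higher and 532 lower in antibody, where 892.95 would be expected with no difference. The test by limma-voom on the recovered reads also called 0 genes, with 1061 at an unadjusted p below 0.05, and with quality weights 0 genes, with 1270. In 199 genes (1.11% of those tested) the groups did not overlap, against 0.794% expected by chance for 5 against 5. The count of 1166 fell to 564 without the 4 libraries highest in the kidney transcript Kap. That setting had fewer libraries in both groups, and no other set of 4 was left out for comparison, so the cause of the fall was not tested. In simulated data of the same depth and spread, 50 well-read genes were changed at each fold, and genes were simulated as independent. There the test recovered 36% of genes changed 1.5-fold, 76% of those changed 2-fold and 92% of those changed 3-fold. Changing many genes at once makes the adjusted threshold easier to pass, and low genes were not among those changed. These shares therefore do not give the chance of finding a few changed genes in the real libraries. Saa3, with a fitted 5.19-fold difference, did not pass (limma adjusted p = 0.739).

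Among the 10 genes of smallest p that were higher in antibody veins, Saa3 had by far the largest difference. Saa3, an inducible serum amyloid A made in inflamed tissue (chromosome 7, 46711998 to 46715676), stood at 119 ± 48.4 RPKM in antibody and 25.0 ± 17.1 RPKM in vehicle veins, a fitted 5.19-fold difference (log2 2.38, SE 0.54, 95% interval 2.26-fold to 11.9-fold, limma adjusted p = 0.739). Antibody replicates 1, 3, 4 and 5 lay between 119 and 164 RPKM, above the highest vehicle value of 47.9 RPKM, while antibody replicate 2 stood at 37.9 RPKM. Cp, which encodes the copper-carrying acute-phase protein ceruloplasmin, was at 15 ± 3.99 RPKM against 8.80 ± 1.55 RPKM. Nfkbiz, an inducible regulator of NF-kappaB target genes, was at 18.7 ± 3.73 RPKM in antibody and 12.4 ± 1.47 RPKM in vehicle veins, with no overlap between the groups. Fgf7, a fibroblast-derived growth factor for epithelium, was at 11.5 ± 1.70 RPKM against 7.6 ± 1.6 RPKM. The leptin receptor Lepr was at 2.18 ± 0.297 RPKM against 1.5 ± 0.20 RPKM. Nlrc5, a transactivator of MHC class I genes, was at 5.35 ± 0.891 RPKM against 3.69 ± 0.425 RPKM. H2-Q10, an MHC class I gene of a family with closely similar members whose reads may be divided among them, was at 1.82 ± 0.555 RPKM against 0.945 ± 0.229 RPKM. Madd (5.35 ± 0.440 against 3.96 ± 0.266 RPKM), the kinase gene Map4k2 (3.77 ± 0.302 against 2.84 ± 0.211 RPKM) and the chromatin remodelling gene Baz1a (11.6 ± 1.86 against 8.41 ± 0.729 RPKM) completed the group. Each of the 10 had an adjusted p of 0.739 and so is given as a value and not as a change.

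Of the genes of smallest p that were lower in antibody veins, 9 are described, with fitted vehicle-to-antibody ratios between 1.3 and 1.63. Arl3, a small GTPase of cilia (chromosome 19, 46531109 to 46573085), was at 19.0 ± 0.549 RPKM in antibody and 26.4 ± 3.42 RPKM in vehicle veins (log2 -0.45, SE 0.10, limma adjusted p = 0.739), with all 5 antibody libraries below the vehicle range. Gstm1, whose gene family has closely similar members, was at 24.5 ± 4.40 RPKM against 35.1 ± 3.68 RPKM. Gamt, the methyltransferase that completes creatine synthesis, was at 4.05 ± 0.774 RPKM against 6.42 ± 1.13 RPKM. Slc27a6, a fatty acid transport gene, was at 0.823 ± 0.186 RPKM against 1.41 ± 0.249 RPKM. The Wnt ligand gene Wnt9b was at 0.500 ± 0.141 RPKM against 1.07 ± 0.298 RPKM, resting on as few as 9 reads in a library. Mapk8ip1, a scaffold of JNK signalling, was at 2.05 ± 0.227 RPKM against 3.32 ± 0.744 RPKM. Ndrg4 (4.08 ± 0.777 against 6.14 ± 0.70 RPKM), Ankrd35 (0.948 ± 0.174 against 1.90 ± 0.525 RPKM) and the mitochondrial import gene Timm17b (3.70 ± 0.488 against 4.95 ± 0.271 RPKM) completed the group. Each had an adjusted p of 0.739.

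**Figure D1:**
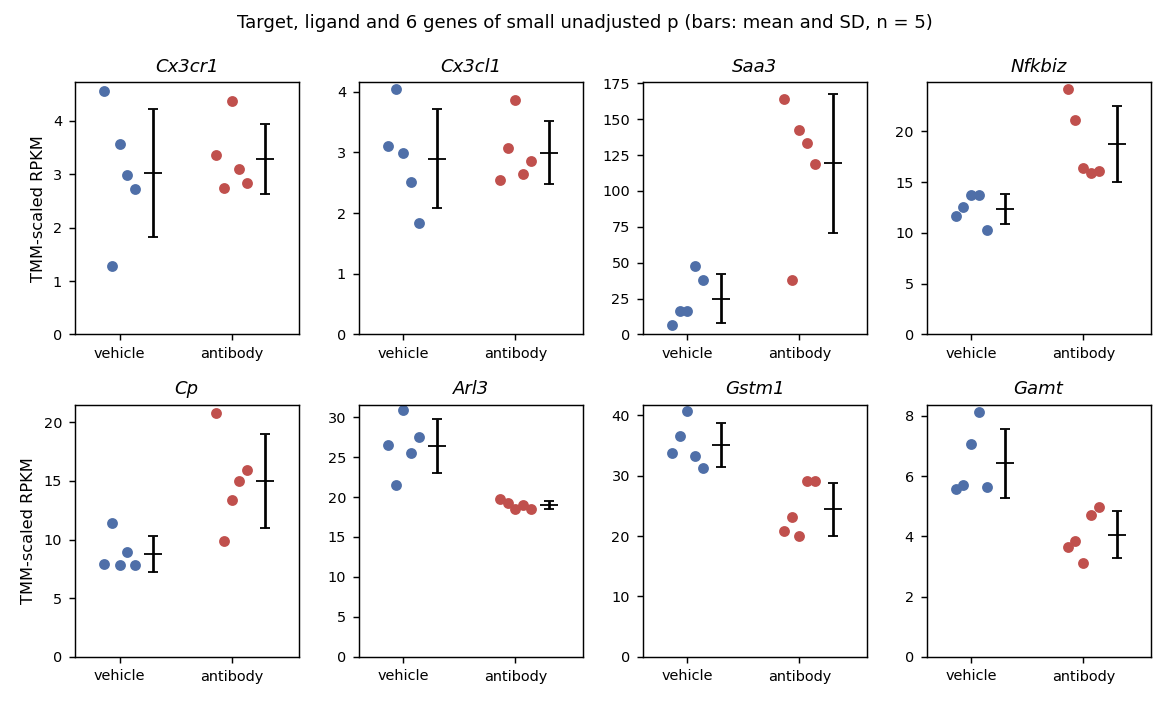
Composition-scaled RPKM (vertical axes, from 0) of the receptor, its ligand and 6 genes with small unadjusted p in each of the 5 vehicle and 5 antibody libraries (points), with the mean and SD of each group (bars). Cx3cr1 and Cx3cl1 overlap between the groups, while 4 of the 5 antibody libraries lie above all vehicle libraries for Saa3 and all 5 lie below them for Arl3.

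Gene lists fixed before the data were examined showed a pattern across cell types under a preset correlation only. Lists of neutrophil, chemokine, T and NK cell and inflammatory genes lay higher in antibody veins, and lists of matrix, fibroblast and smooth muscle genes lay lower, relative to other genes. With camera and a preset correlation of 0.01, 14 of the 30 lists tested had an adjusted p below 0.05, 7 higher and 7 lower in antibody. The preset value was too low for these lists. Their estimated correlations ran from 0.0449 (nerve and Schwann cell genes) to 0.844 (skeletal muscle genes). Other splits of the libraries, which ignore treatment, called a median of 10 lists. With a correlation estimated for each list, 0 of the 30 passed (smallest adjusted p = 0.433 with an estimated correlation), and 0 passed by fry, which asks whether a list's genes move on balance in one direction (smallest adjusted p = 0.329). No member of any list passed when adjusted over all genes, and adjusted over the list alone only Bmp2, in the osteochondrogenic list, had a value below 0.05. The exact permutation test on the libraries' list means gave its smallest p, 0.0397, for the fibroblast list and for the synthetic smooth muscle list.

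Neutrophil genes lay higher in antibody veins, with the 3 highest of the 10 library means in antibody replicates 1, 2 and 3. Of 10 measured members 9 had a higher mean in antibody, the mean log2 difference was 0.92 (SE 0.43 between libraries), and camera gave adjusted p = 0.000739 (adjusted p = 0.433 with an estimated correlation). Cxcr2, the neutrophil chemokine receptor, was at 5.70 ± 3.66 RPKM in antibody and 1.48 ± 1.23 RPKM in vehicle veins. Csf3r, the receptor of the neutrophil growth factor G-CSF, was at 26.8 ± 14.4 against 11.4 ± 4.49 RPKM, the decoy receptor gene Il1r2 at 8.92 ± 6.52 against 2.91 ± 1.36 RPKM, and the calprotectin subunit gene S100a8 at 53.8 ± 39.7 against 19.6 ± 15.4 RPKM. Chemokines and their receptors lay higher in 24 of 27 measured members (mean log2 0.41, SE 0.25, camera adjusted p = 0.000418, adjusted p = 0.433 with an estimated correlation). The members of smallest p were Cxcl12, a stromal chemokine (47.1 ± 13.6 against 26.1 ± 8.44 RPKM), the neutrophil attractants Cxcl1 (33.2 ± 17.5 against 13.9 ± 5.84 RPKM) and Cxcl5 (27.2 ± 16.3 against 7.77 ± 6.62 RPKM), and Cxcr2, which the list shares with the neutrophil list. For both lists 0 members passed when adjusted over all genes and 0 when adjusted over the list alone. The chemokine difference depended in size on single libraries, with a mean log2 of 0.27 without vehicle replicate 2 and 0.27 without antibody replicate 1.

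Inflammatory cytokine and NF-kappaB genes lay higher in 16 of 21 measured members (mean log2 0.35, SE 0.25, camera adjusted p = 0.00386, adjusted p = 0.569 with an estimated correlation). The interleukin gene Il1b was at 47.0 ± 30.3 RPKM in antibody and 14 ± 12.2 RPKM in vehicle veins, Il6 at 5.88 ± 3.76 against 2.48 ± 1.03 RPKM, the NF-kappaB subunit gene Relb at 9.22 ± 1.49 against 6.96 ± 1.25 RPKM and Selp, encoding the adhesion molecule P-selectin, at 15.9 ± 6.15 against 8.49 ± 3.87 RPKM. T and NK cell markers lay higher in 14 of 17 members (mean log2 0.40, SE 0.30, camera adjusted p = 0.000971, adjusted p = 0.433 with an estimated correlation), among them Cd3d (0.942 ± 0.498 against 0.421 ± 0.171 RPKM) and Cd2 (2.84 ± 1.58 against 1.37 ± 0.570 RPKM). Genes of classically activated macrophages lay higher in 9 of 12 members (mean log2 0.38, SE 0.24, camera adjusted p = 0.0258, adjusted p = 0.433 with an estimated correlation), led by Il6 and Il1b, which the inflammatory list also holds, and Nos2 (1.77 ± 0.460 against 1.26 ± 0.294 RPKM). In these 3 lists 0 members passed when adjusted over all genes and 0 when adjusted over the list alone. Antibody replicate 1 carried much of the difference: without it the mean log2 was 0.16 for T and NK cell markers (camera adjusted p = 0.0757), 0.20 for inflammatory genes (0.149) and 0.25 for classically activated macrophage genes (0.153), and the last list was also lost without antibody replicate 3 (0.104), vehicle replicate 2 (0.122) or vehicle replicate 5 (0.0563). The classically activated macrophage call was lost as well with limma-voom, with quality weights and with the muscle level as a covariate.

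Matrix and mural cell genes lay lower in antibody veins by small amounts. Fibrillar and basement membrane matrix genes were lower in 24 of 27 members (mean log2 -0.20, SE 0.09, camera adjusted p = 0.000739, adjusted p = 0.433 with an estimated correlation), with the collagen genes Col6a2 at 158 ± 16.1 against 218 ± 45.1 RPKM, Col6a1 at 289 ± 28.9 against 370 ± 75.5 RPKM and Col5a2 at 231 ± 22.1 against 289 ± 52.3 RPKM, and the matricellular gene Tnc at 98.0 ± 19.8 against 134 ± 39.7 RPKM. Fibroblast markers were lower in 14 of 15 members (mean log2 -0.29, SE 0.11, camera adjusted p = 0.000739, adjusted p = 0.433 with an estimated correlation), led by the microfibril gene Mfap5 (30.1 ± 4.42 against 46.9 ± 12.9 RPKM), Loxl1, which cross-links elastin (80.7 ± 7.80 against 109 ± 22.8 RPKM), and Gsn (234 ± 75.4 against 365 ± 113 RPKM). The list shares 3 collagen genes with the matrix list. Synthetic smooth muscle and myofibroblast genes were lower in 13 of 15 members (mean log2 -0.22, SE 0.09, camera adjusted p = 0.00714, adjusted p = 0.433 with an estimated correlation), among them Mgp, an inhibitor of calcification (424 ± 52.7 against 663 ± 221 RPKM), and Fn1 (468 ± 72.9 against 584 ± 131 RPKM). Contractile smooth muscle genes were lower in 14 of 15 members (mean log2 -0.29, SE 0.15, camera adjusted p = 0.00508, adjusted p = 0.433 with an estimated correlation), among them Smtn (23.8 ± 2.36 against 29.1 ± 4.64 RPKM) and Tagln (70.2 ± 19.6 against 88.7 ± 16.6 RPKM), while Mylk stood at 14.6 ± 2.51 against 12.2 ± 1.73 RPKM. In these 4 lists 0 members passed when adjusted over all genes and 0 when adjusted over the list alone. The contractile list was lost without vehicle replicate 2 (camera adjusted p = 0.122), and the contractile and fibroblast lists without the 4 libraries highest in Kap (0.0726 and 0.0676).

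The other lists past the preset-correlation test concerned osteochondrogenic, neural, lymphatic, skeletal muscle and sex-linked genes. Osteochondrogenic and calcification genes were lower in 8 of 13 members (mean log2 -0.13, SE 0.15, camera adjusted p = 0.0370, adjusted p = 0.433 with an estimated correlation); Bmp2, a bone morphogenetic protein, was at 2.50 ± 0.622 RPKM in antibody and 4.18 ± 0.852 RPKM in vehicle veins (limma, 0.0473 adjusted over the list alone, 0.739 adjusted over all genes). Nerve and Schwann cell genes were lower in 9 of 12 members (mean log2 -0.17, SE 0.07, camera adjusted p = 0.0282, adjusted p = 0.433 with an estimated correlation), with the neurofilament genes Nefm (0.144 ± 0.0473 against 0.383 ± 0.197 RPKM) and Nefl (0.173 ± 0.123 against 0.571 ± 0.381 RPKM) near the low end of the measured range. All 7 lymphatic endothelial markers were higher (mean log2 0.26, SE 0.22, camera adjusted p = 0.0391, adjusted p = 0.433 with an estimated correlation), among them Flt4 (5.81 ± 1.61 against 4.37 ± 1.10 RPKM) and Prox1 (2.78 ± 1.08 against 1.86 ± 0.845 RPKM). Skeletal muscle genes were lower in 14 of 16 members (mean log2 -0.70, SE 0.83, camera adjusted p = 0.00508, adjusted p = 0.569 with an estimated correlation), and the exact permutation test of the library means gave p = 0.381. The 4 Y-linked genes measured were each higher (mean log2 0.16, SE 0.07, camera adjusted p = 0.0179, adjusted p = 0.433 with an estimated correlation), for example Uty at 4.15 ± 0.250 against 3.39 ± 0.487 RPKM. Apart from Bmp2, 0 members of these 5 lists passed when adjusted over the list alone. Each of the 5 calls was lost on leaving out a single library, and the highest camera adjusted p so reached was 0.276 for osteochondrogenic genes (without vehicle replicate 2, mean log2 -0.05), 0.0861 for nerve genes (without antibody replicate 3), 0.327 for lymphatic genes (without antibody replicate 5, mean log2 0.11), 0.285 for skeletal muscle genes (without vehicle replicate 4, mean log2 -0.24) and 0.0586 for Y-linked genes (without antibody replicate 5). The sizes of the skeletal muscle and osteochondrogenic differences were unstable in the other direction as well, at -1.15 without antibody replicate 5 and -0.25 without vehicle replicate 5.

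**Figure D2:**
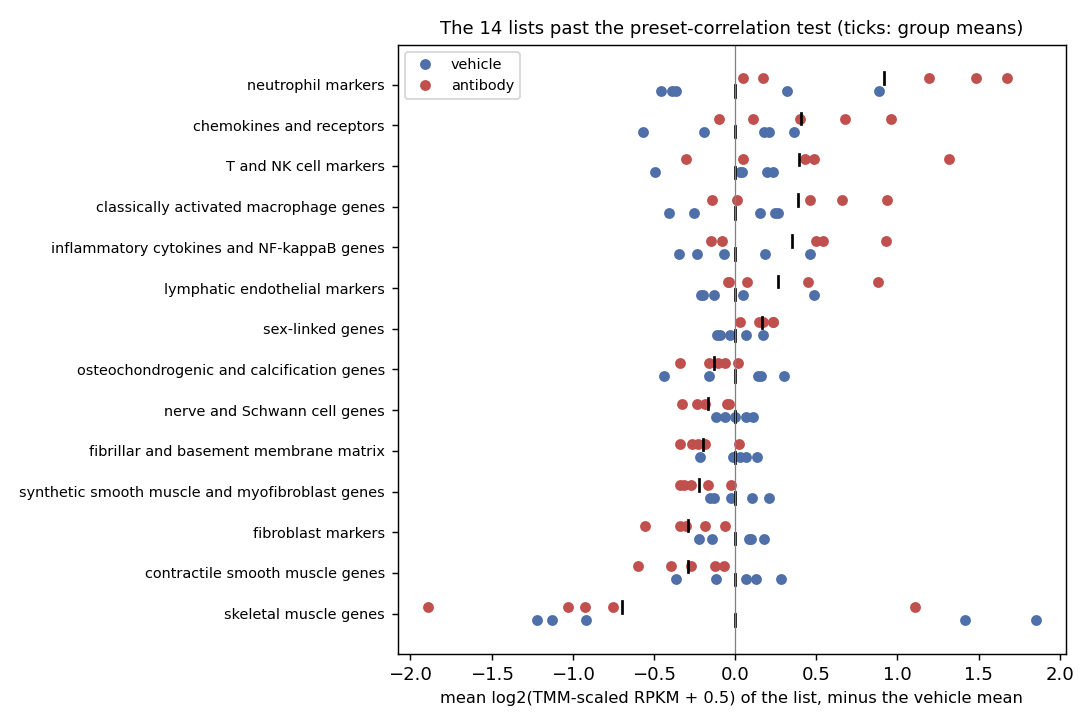
Mean log2(RPKM + 0.5) of each list in each library minus the vehicle mean (horizontal axis) for the 14 lists past the preset-correlation test (vertical axis), with 5 vehicle and 5 antibody libraries as points and group means as ticks. The neutrophil list has the widest separation of group means, 0.92, with antibody replicates 1, 2 and 3 above all vehicle libraries, while the libraries of the groups overlap in each list.

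The remaining 16 lists did not pass. General monocyte and macrophage markers, the cells that carry the receptor, were lower in 12 of 20 members (mean log2 -0.06, SE 0.15, camera adjusted p = 0.482); the complement gene C1qc was at 89.5 ± 12.4 RPKM in antibody and 126 ± 31.9 RPKM in vehicle veins and the integrin gene Itgam at 33.8 ± 8.71 against 27.1 ± 3.53 RPKM. Genes of alternatively activated macrophages were lower in 10 of 13 members (mean log2 -0.25, SE 0.13, camera adjusted p = 0.0634), though Arg1 stood at 12.6 ± 7.22 against 6.01 ± 4.71 RPKM. Proliferation genes were higher in 15 of 25 members with a mean log2 difference of 0.00 (SE 0.22, camera adjusted p = 0.943). TGF-beta pathway genes were lower in 13 of 18 members (mean log2 -0.15, SE 0.10, camera adjusted p = 0.0634), with Tgfb3 at 26.0 ± 4.62 against 34.0 ± 4.14 RPKM. Endothelial markers were higher in 11 of 16 members (mean log2 0.06, SE 0.09, camera adjusted p = 0.315), with the VEGF receptor gene Kdr at 17.8 ± 2.09 against 13.4 ± 2.18 RPKM. The camera adjusted p was 0.0634 for cardiac muscle genes, 0.0869 for erythroid and platelet genes, 0.117 for B and plasma cell markers, 0.197 for immediate early genes, 0.296 for epithelial genes and for hypoxia and angiogenesis genes, 0.460 for mast cell markers, 0.471 for dendritic cell markers and 0.943 for interferon response genes. For adipocyte genes the adjusted p was 0.870, and the mean (0.15) and median (-0.04) log2 differences differed in sign. Matrix proteases and their inhibitors had an adjusted p of 0.965 with a mean of 0.03, a median of -0.03 and a test direction of lower. Each of the 16 lists had 0 members past the threshold when adjusted over all genes and 0 when adjusted over the list alone.

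Before any test between groups, the libraries were laid out by their 500 most variable genes. Component 1 held 36.1% of the variance and was led by skeletal muscle transcripts such as Sln, Myh2 and Mb, with antibody replicate 5, vehicle replicate 4 and vehicle replicate 5 at its high end. The groups did not separate on it (exact two-sided permutation p = 0.230). Component 2 held 22.2% and was led by kidney transcripts such as Kap, Slc34a1, Lrp2 and Umod together with small RNA genes, with antibody replicate 4 and vehicle replicate 1 highest (exact permutation p = 0.952). The fixed skeletal muscle list took 1.27% of reads in antibody replicate 5, 2.38% in vehicle replicate 4 and 1.12% in vehicle replicate 5, and 0.121% to 0.393% in the other 7 libraries. The muscle actin gene Acta1 stood at 1256, 1593 and 1327 RPKM in those 3 libraries and at 104 to 280 RPKM in the others.

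**Figure D3:**
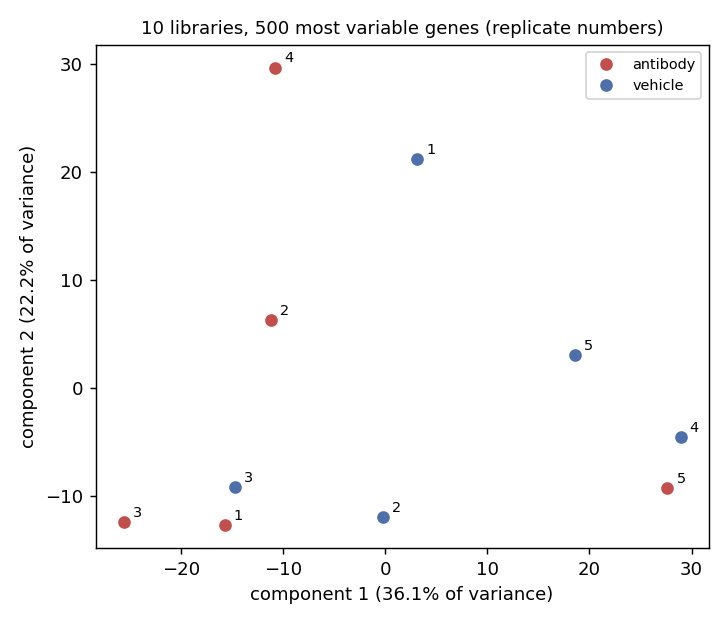
Positions of the 10 libraries on components 1 and 2 (axes, arbitrary units, with the share of variance) of the 500 most variable genes, coloured by group and marked with the replicate number. The groups intermix: antibody replicate 5 lies with vehicle replicates 4 and 5 at the high end of component 1.

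**Figure D4:**
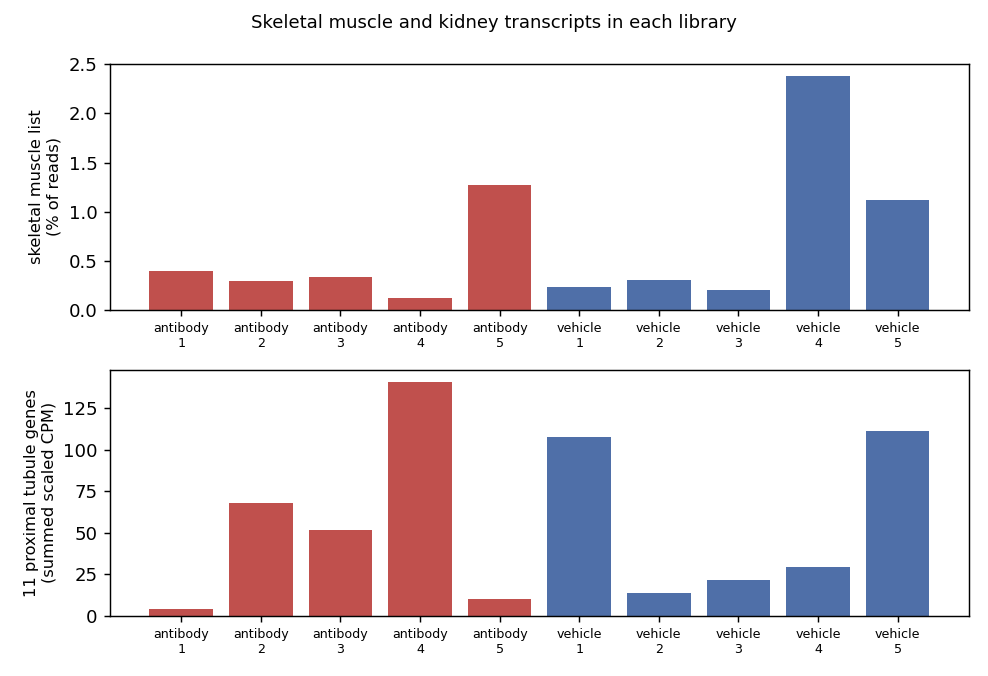
Percent of reads on the fixed skeletal muscle list (upper bars) and summed scaled CPM of 11 proximal tubule genes (lower bars) in each of the 10 libraries, coloured by group. Skeletal muscle reads are highest in antibody replicate 5 and vehicle replicates 4 and 5, and proximal tubule transcripts range from 3.86 to 141 CPM.

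Statistics for the comparison are also part of the authors' deposited table, with a fold change of mean RPKM and an unadjusted p per gene. Of 39673 genes with a p in the authors' deposited table, 1564 had a p below 0.05, 858 with a fold above 1 and 703 below 1, where 1983.65 would be expected with no difference. After Benjamini-Hochberg adjustment, 0 of the p-values in the authors' deposited table fell below 0.05, and the smallest was 0.506. Among the 17859 genes tested here, 924 had a p below 0.05 in the authors' deposited table and 682 of these also had one in the limma test. For Saa3 the authors' deposited table gives a fold of 5.16 with p = 0.00412, and for Cx3cr1 a fold of 1.15 with p = 0.524, both without permutation and unadjusted.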

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

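The tests of depth, of muscle content, of skeletal muscle and kidney transcripts, and the split count for genes past the adjusted threshold were chosen only after the result was seen; for depth and muscle content as sources of the list differences, the bounds were written before those tests were run.

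Of 100 groups of 5 libraries examined for a library standing apart from the other 4, 6 did so, where chance gives about 1 in 20. In antibody veins the share of reads on the skeletal muscle list was 1.27% in antibody replicate 5 against at most 0.393% in the others (gap of 0.763 of the range), and the same library stood apart on component 1 at 27.6 against -25.6 to -10.8 (gap of 0.722). Rn7sk, Rpph1 and Rmrp took 2.18% of reads in antibody replicate 3 against 0.979% to 1.26% (gap of 0.764). Mapk8ip1 stood at 2.44 RPKM in antibody replicate 4 against 1.87 to 2.02 RPKM (gap of 0.727). The mean log2 level of T and NK cell markers was -0.10 in vehicle replicate 2 against 0.42 to 0.62 in the other vehicle libraries (gap of 0.723). In vehicle replicate 5, 17796 of the tested genes had a read against at least 17846 in the other vehicle libraries (gap of 0.806).

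Neutrophil genes lay higher and matrix genes lower in antibody veins under the preset correlation, while no gene was called and both lists were lost with an estimated correlation (adjusted p = 0.433 with an estimated correlation for each). With all libraries thinned to the same number of reads over 5 draws, 106% of the neutrophil difference was left (94.0% to 109%) and 96.1% of the matrix difference (93.6% to 101%). This speaks only to the number of reads counted. Thinning hardly moves the expected level of well-read genes, and antibody replicate 3 already stood at the target. Traits of a library that go with low depth were therefore not tested. By its test a linear effect of muscle content did not account for the differences: with the muscle level as a covariate 105% and 114% of the neutrophil and matrix differences were left. These shares come from 10 libraries and have no interval, so a part played by muscle content cannot be excluded. Chance could not be excluded: of 100 splits of the libraries, the real one included, 10 gave at least the real 14 lists (highest other 19) and 24 at least the real 1166 genes at an unadjusted p below 0.05 (highest other 2249). For genes past the adjusted threshold the comparison tests nothing, since the real count is 0 and all 100 splits must reach it (highest other 12). Whether the antibody itself shifted these lists stays open, since a split of the libraries that ignores treatment can give as many lists.

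Skeletal muscle transcripts were high in antibody replicate 5 and vehicle replicates 4 and 5. Both groups held low and high libraries, so a high level did not require either treatment. The range within each group was wider than the difference between the means, and the exact permutation p of the list means was 0.381. With a mean log2 difference of -0.70 and an SE of 0.83, a part played by treatment cannot be excluded. Muscle tissue taken with the vein is a candidate source: over the 10 libraries the 16 list genes moved together with a median pairwise Spearman correlation of 0.770, and the abundant muscle genes Acta1 and Ckm reached 1593 and 764 RPKM in vehicle replicate 4. These libraries did not stand apart in contractile smooth muscle genes, the muscle type of the vein wall. The mean log2 level of that list was 4.03 in antibody replicate 5, 4.17 in vehicle replicate 4 and 4.23 in vehicle replicate 5. In the other libraries it ran from 3.51 to 4.38. Differences in the vein wall muscle were not tested further.

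Kidney transcripts, absent from the fixed lists, led component 2. Summed over 11 proximal tubule genes they ranged from 3.86 CPM in antibody replicate 1 to 141 CPM in antibody replicate 4, with 108 CPM in vehicle replicate 1 and 111 CPM in vehicle replicate 5, and the most abundant, Kap, reached 49.5 RPKM. Both groups held low and high libraries, so a high level did not require either treatment (exact permutation p = 0.698). With a spread this wide, the test cannot exclude a part played by treatment. Kidney tubule RNA in the libraries, from tissue carried over or from libraries handled together, is a candidate source: 7 loop and distal tubule genes followed the proximal genes with Spearman's rho of 0.964 (permutation p = 3e-05, adjusted 0.00012 over 4 relations) and Pearson's r of 0.94 (permutation p = 0.00043, adjusted 0.00172), r being 0.927 without antibody replicate 4 and vehicle replicate 5. Of 19 marker genes besides Kap, 14 had a rho above 0.7 with Kap, while Nphs1, a gene of glomerular filter cells read 103 times in all, had a rho of 0.297, so the relation is shown for tubule genes only. The route by which such RNA came in was not tested.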

How the results depend on the processing

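The pseudocounts, protein-coding, muscle, kidney and thinning settings were chosen after seeing the data. The count of 0 genes past the threshold held in each setting but the omission of the low-value filter, which called 1 gene of 39673, the miRNA-type gene Gm27598 (adjusted p = 0.0412), with 0 reads in all antibody libraries and 1 or 2 reads in each vehicle library, below the limit of 3. That setting tested more genes and gave 1910 at an unadjusted p below 0.05; leaving out the 4 libraries highest in Kap gave 564, with fewer samples; leaving out single libraries gave 779 to 1500. The number of lists called was 0 with an estimated correlation and 0 by fry, 18 with library totals only and 10 to 17 on leaving out single libraries; the neutrophil, chemokine, matrix and synthetic smooth muscle calls held in the 24 other settings with the preset correlation. For lymphatic genes the mean log2 difference was -0.00236 without the 3 muscle-rich libraries (camera adjusted p = 0.986). The lymphatic call was also lost with the replicate block, with quality weights and with thinning. Cx3cl1 changed sign with limma-voom (-0.00653), the muscle covariate (-0.0163), the muscle-rich (-0.140) or the Kap-rich (-0.0385) libraries left out, and ranged from -0.0664 (without vehicle replicate 5) to 0.179 on leaving out single libraries, being -0.0175 without antibody replicate 3, as Cx3cr1 did from -0.0601 (without vehicle replicate 2) to 0.314; the cause was not tested, and no value was near the threshold. The 20 genes named by p kept their sign and stayed above the threshold in all 440 comparisons, and components stayed above it in all 24. Thinning and the omission of the Kap-rich libraries were not applied to these 20 genes. The genes were picked by p from the same libraries, and almost no setting called any gene. Their outcome was thus largely fixed in advance. With the replicate number as a block, 0 genes and 15 lists were called (1252 genes at an unadjusted p below 0.05). Whether the numbers pair animals is not given by the labels. Correlations of same-numbered deviations ran from -0.0953 to 0.347, and only replicate 3 correlated best with its own number both ways. Paired animals need not have correlated deviations, so these values do not settle it. The edgeR test planned for raw counts, its form without robust and DESeq2 were not run, because the table was in RPKM. The recovered reads would have allowed them. The filter asks 5 of 10 libraries to reach 0.513 CPM, so genes below the 3-read limit of the shallowest library were kept.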

Other observations

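The correlations of the neutrophil list were chosen only after the result was seen.

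Brown fat and blood transcripts varied between libraries of a group, and Ucp1 was above all vehicle libraries in each antibody library except replicate 2. Ucp1, the heat-producing uncoupling protein of brown fat, stood at 51.2 RPKM in antibody replicate 1, 21.8 in antibody replicate 4, 3.88 in antibody replicate 5 and 1.77 in antibody replicate 3, and at 0.113 to 0.950 RPKM in the vehicle libraries, while antibody replicate 2 was at 0.350 RPKM. The adipocyte gene Adipoq was at 150 RPKM in antibody replicate 4 and 16.2 RPKM in antibody replicate 3. The haemoglobin gene Hbb-bs ranged from 82.1 RPKM in vehicle replicate 2 to 679 RPKM in vehicle replicate 1. Vehicle replicate 2 was also lowest of the 10 in the neutrophil, chemokine, inflammatory, classically activated macrophage, T and NK, B and plasma, dendritic, mast cell, interferon and erythroid lists, and had the lowest Cx3cr1.

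Within the antibody group, neutrophil genes and Saa3 did not follow each other. S100a9 stood at 117, 129 and 203 RPKM in antibody replicates 1, 2 and 3 and at 24.9 and 21.3 RPKM in antibody replicates 4 and 5, whereas Saa3 was low in antibody replicate 2 alone. Over all 10 libraries the neutrophil list mean and Saa3 had r = 0.597 (permutation p = 0.0718, adjusted 0.133 over 4 relations) and rho = 0.673 (permutation p = 0.0389, adjusted 0.0778). Without antibody replicates 1 and 3, the farthest from the median, r was 0.314, and r was -0.0539 within antibody and 0.537 within vehicle libraries. The neutrophil and matrix list means had r = -0.548 (permutation p = 0.0995, adjusted 0.133) and rho = -0.491 (permutation p = 0.154, adjusted 0.206), with r = -0.273 without the same 2 libraries, 0.104 within antibody and -0.769 within vehicle libraries.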
